A study of Homo sapiens with 9 samples.

How the data were processed

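RNA from HepG2 cells was hybridised to 9 Affymetrix arrays, 1 per sample, with biotin labelling per the labels. Samples were grouped by their titles together with the stated design of 4 controls and 5 knockdowns: titles that name the vector or a vector abbreviation are control arrays, and the remaining 5 are knockdown arrays. Replicate numbers came from the titles where they were given; 2 knockdown titles share the number 2, and one of these is called knockdown 3, the number no other knockdown title held. The level of the targeted gene is not reported here, so the labels were not checked by it, and 1 of the 10 genes fixed by name was not analysed here.

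The deposited values are intensity values, 1 per probe set and array, on a linear scale with 1 decimal, and 8 of them are 0. The labels name the RNA extraction kit and the Affymetrix labelling kit. The summary method, software and scaling by which the authors made the intensity values are not given in the sources used here, and no detection calls were used here. Array medians spanned a factor of 2.09, and a difference of scanner gain or labelling between arrays would enter such values as a common factor. A rule fixed before the data were examined applied quantile normalization when the span exceeded 2, so the 9 arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Quantile normalization gives all arrays the same distribution and would remove a real global shift. Signals were then converted to log2(signal + 16), on which a signal of 0 is 4. Adding 16 keeps noise of dim probe sets from giving large folds, and it understates changes of dim probe sets.

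Gene names came from the platform annotation given for these probe sets, in which 19064 probe sets had 1 gene symbol, 1043 had several and 2108 had none, besides 62 control probe sets. Entrez identifiers of 19052 probe sets were found in the RefSeq gene table and 0 symbols needed an update. No gene was named from a probe set with several symbols, and 11963 genes had a probe set of their own. Control probe sets and the 25% of probe sets with the lowest mean over all 9 arrays were left out, which left 16661 probe sets and 9543 genes.

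Groups were compared with limma (lmFit and eBayes with trend, knockdown minus control, no covariate), with Benjamini-Hochberg adjustment over the 16661 probe sets, a threshold of 0.05 and intervals of 95%. Gene lists were tested with camera in limma at its preset correlation of 0.01, on the brightest tested probe set of each gene, with adjustment over the 22 lists, and again with an estimated correlation and with fry. The lists were tight junction, adherens junction and desmosome, bile canaliculus and apical polarity, basolateral liver transport, liver secreted proteins, liver transcription factors, mesenchymal and EMT, integrin and matrix adhesion, actin and small GTPase, WNT and beta-catenin targets, cholesterol synthesis, bile acid synthesis, drug metabolism, interferon response, cell cycle, p53 targets, integrated stress and unfolded protein response, hypoxia, and markers of endothelium, leukocytes, fibroblasts, and neural and kidney epithelium. They held 472 genes from background knowledge, of which 405 were named in the annotation and 355 were tested.

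The named genes followed a rule fixed before the data were examined. It takes every probe set of the targeted gene, up to 10 genes per direction with the largest change among probe sets past the threshold whose groups do not overlap, up to 4 passing members of each list or else its member with the smallest p, and 10 genes fixed by name; 1 list member that the rule takes is not reported here. Exact permutation tests over all splits of the 9 arrays into 5 and 4 were two-sided.

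Array sets were defined after the data were seen, at the largest gap in the signal of the ribosomal RNA control probe sets over the array median. The alternatives planned beforehand were pseudocounts of 1 and 64, the deposited scaling, median scaling, no filter and a 50% filter on dim probe sets, limma without trend, with robust variances and with array weights, the title number and the title style as blocks, each array left out, stricter thresholds, an estimated correlation, fry, and the mean over a gene's probe sets. The array set as a block, the low ribosomal RNA set alone and the GAPDH ratio as a covariate were added after the data were seen.

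The limma step was tested on simulated arrays with the real means and spread of the 16661 probe sets, 5 against 4. It recovered 10% of 50 probe sets changed 1.5-fold, 50% of 50 changed 2-fold, 98% of 50 changed 4-fold and 100% of 50 changed 8-fold, with 2 wrong calls, and called 0 when nothing was changed. The list step called a list shifted by 0.5 and 0 other lists, on 9543 genes. All genes were drawn independently, without the correlation between genes or the array sets of the real arrays. Neither step was thus tested against those 2 features. Figures were drawn with matplotlib 3.10.9.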

Results

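Gene expression was measured in HepG2 cells, an established human liver tumour line that keeps many hepatocyte features and forms bile canaliculus-like lumens between neighbouring cells. The cells had been transduced with lentivirus and kept under puromycin selection. JAM-A, the protein targeted by the knockdown, is a transmembrane adhesion protein of epithelial tight junctions. There were 5 arrays of JAM-A knockdown cells and 4 arrays of vector control cells. Each array gave a signal for 22277 probe sets, which are groups of oligonucleotides that report 1 or more transcripts. The median signal of the deposited values lay between 14.1 (knockdown 1) and 29.5 (knockdown 4). An array has no sequencing depth, and the number of arrays limits the precision. The labels do not say that the arrays came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The comparison asks which transcripts differ when JAM-A is reduced in hepatic cells, with cell junctions, cell polarity and liver functions as the background of the question.

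The arrays fell into 2 sets that did not follow the groups. In control 2, control 3 and knockdown 3 the ribosomal RNA control probe sets gave 21.3, 11.2 and 18.5 times the array's median signal. In the other 6 arrays the same ratio lay between 1.43 (control 4) and 3.34 (knockdown 2). The 3-array set is called the high ribosomal RNA set and the 6-array set the low ribosomal RNA set. The ratio of 3′ to 5′ GAPDH control signal, which increases when RNA is degraded or incompletely copied, was 0.942 to 1.04 in the high set and 1.17 to 2.11 in the low set. The first principal component held 42.4% of the variance and separated these sets, and the PC2 share was 15.5%. Inside the low set, knockdown 1, knockdown 2 and knockdown 4 lay at -35.5, -36.8 and -22.7 on the first component. Control 1, control 4 and knockdown 5 lay at -5.06, -9.37 and -8.79. In the high set, knockdown 3 lay at 34.4, below control 2 at 42.3 and control 3 at 41.5. This component was thus not free of the groups inside the sets. Across probe sets, the median Pearson correlation was 0.974 for pairs of arrays within a set and 0.960 for pairs across sets, against 0.967 within a group and 0.963 across groups. No pair exceeded 0.984, and no array was counted as a repeat of another. The GAPDH ratio was 1.76 ± 0.434 (SD, n = 5) in knockdown and 1.29 ± 0.504 (SD, n = 4) in control arrays, a difference that did not pass a two-sided exact permutation test (p = 0.167, adjusted p = 0.611 over 4 array measures). The actin 3′ to 5′ ratio, the ribosomal RNA ratio and the median signal did not pass it either (exact p = 0.468, 0.548 and 0.611, each with an adjusted p of 0.611). The smallest p that the splits of 9 arrays can give is 0.0079.

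**Figure D1:**
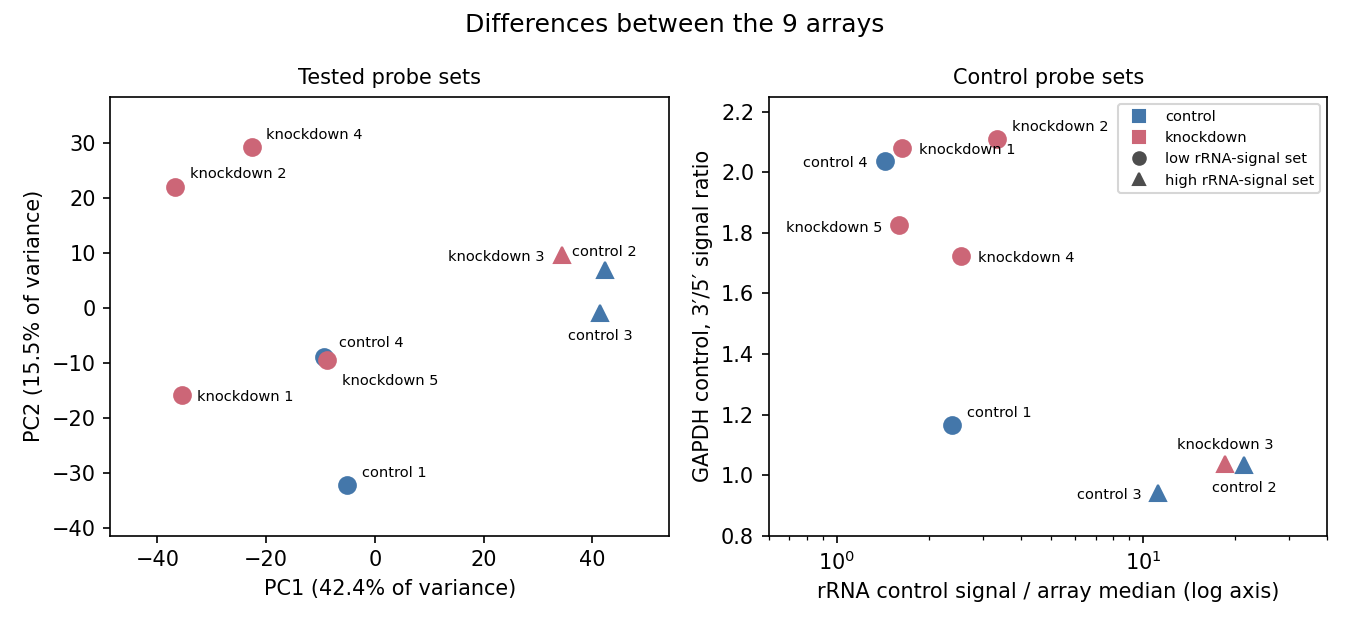
The left panel plots the 9 arrays on the first and second principal components of the log2 signals of the tested probe sets, and the right panel plots each array's ribosomal RNA control signal over its median signal (log axis) against its 3′ to 5′ GAPDH signal ratio. Colour marks the group and shape marks the array set; control 2, control 3 and knockdown 3 lie apart from the other 6 arrays in both panels, with both groups present in each set.

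CDH1, which encodes E-cadherin, the main adhesion protein of epithelial adherens junctions, was the transcript that differed most strongly. Its signal was 428 ± 214 (SD, n = 5) in knockdown and 31.7 ± 15.4 (SD, n = 4) in control arrays, and all 5 knockdown arrays lay above all 4 control arrays. SCNN1A, which encodes the alpha subunit of the epithelial sodium channel, rose from 18.2 ± 9.85 (SD, n = 4) to 94.9 ± 28.8 (SD, n = 5). SRM, which encodes spermidine synthase, an enzyme of polyamine synthesis, fell from 309 ± 57.2 (SD, n = 4) to 103 ± 29.6 (SD, n = 5). DESI2, which encodes a desumoylating isopeptidase, fell from 269 ± 13.3 (SD, n = 4) to 78.2 ± 30.6 (SD, n = 5), and SLC25A14, which encodes a mitochondrial inner membrane carrier, fell from 27.0 ± 5.49 to 4.35 ± 2.54. The junction genes OCLN, TJP1, CLDN1 and CTNNB1 and the liver genes ALB and ABCC2 did not pass the test.

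**Figure D2:**
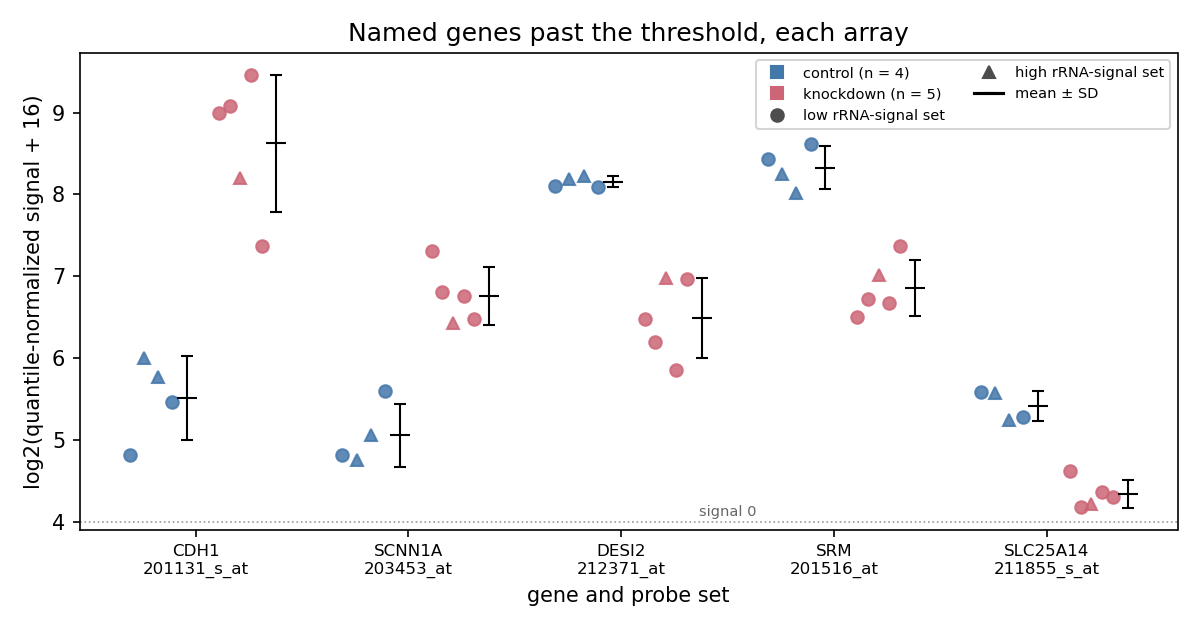
Each point is 1 array's log2 signal (quantile normalized, with 16 added) for the 5 named genes that passed the limma test, with control arrays in blue and knockdown arrays in red, and shape marking the array set. Black bars are the group mean ± SD (n = 4 control, n = 5 knockdown), the dotted line is a signal of 0, and in each gene all knockdown arrays lie on one side of all control arrays.

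In limma, 6 of 16661 probe sets passed an adjusted p of 0.05: 2 rose and 4 fell, of which 1 that fell carried no gene name here. CDH1 (probe set 201131_s_at) rose by 3.11 on the log2 scale (SE 0.376, 95% interval 2.30 to 3.92, 8.64-fold, adjusted p = 0.0166). SCNN1A (203453_at) rose by 1.70 (SE 0.232, 3.25-fold, adjusted p = 0.0327). DESI2 (212371_at) changed by -1.66 (SE 0.236, 3.16-fold lower, adjusted p = 0.0327), SRM (201516_at) by -1.47 (SE 0.214, 2.78-fold lower, adjusted p = 0.0327) and SLC25A14 (211855_s_at) by -1.08 (SE 0.16, 2.11-fold lower, adjusted p = 0.0334). Because the groups did not overlap in any of these 5 genes, each difference had to keep its sign within both array sets. The CDH1 difference was 3.59 in the low and 2.31 in the high ribosomal RNA set, which holds 1 knockdown array. That of SCNN1A was 1.63 and 1.53, and that of SRM -1.71 and -1.11. For DESI2 the differences were -1.73 and -1.23, and for SLC25A14 -1.06 and -1.19. Folds are on the log2(signal + 16) scale, which understates changes of dim probe sets, and the knockdown signal of SLC25A14 was close to 0. With the array set as a block, a setting added after the data were seen, 7 probe sets passed, among them all 6.

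Other probe sets of the same genes had differences of the same sign that did not pass. For CDH1, 201130_s_at lay near the bottom of the scale, at a log2 signal of 4.83 ± 0.55 (SD, n = 5) against 4.38 ± 0.15 (SD, n = 4), and differed by 0.45 (limma adjusted p = 0.642). The 2 other DESI2 probe sets differed by -1.46 and -0.79, another of SLC25A14 by -0.53, and another of SCNN1A by 0.15. At an unadjusted p under 0.05 there were 1349 probe sets, or 8.10% of those tested. In 395 probe sets (2.37%, where chance gives 1.59%) the groups did not overlap, with 218 higher and 177 lower in knockdown arrays.

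The number of passing probe sets rested on single arrays. It was 0 without control 1, control 3, knockdown 1, knockdown 2 or knockdown 4, with 847 to 1432 at an unadjusted p under 0.05. It was 3 without control 2 (924 unadjusted), 1 without control 4 (1940), 36 without knockdown 3 (2523) and 4 without knockdown 5 (1332). Knockdown 3 is the only knockdown array of the high ribosomal RNA set. Every fit without it, for the count and for single genes, thus mixes group with array set. For CDH1 the log2 difference stayed between 2.87 and 3.41 in these fits, with an adjusted p of 0.0571 without control 1, 0.0576 without control 3, 0.0570 without control 4, 0.0514 without knockdown 1, 0.0880 without knockdown 2 and 0.0553 without knockdown 4. SCNN1A stayed between 1.59 and 1.85 but passed only without control 4, knockdown 3 or knockdown 5, with an adjusted p of 0.0514 to 0.143 in the other 6 fits. DESI2 (-1.79 to -1.50) and SRM (-1.59 to -1.38) passed only without knockdown 3 or knockdown 5, with an adjusted p of 0.0684 to 0.147 and 0.0741 to 0.147 otherwise. SLC25A14 (-1.18 to -1.04) passed only without knockdown 3, with an adjusted p of 0.0514 to 0.151 otherwise. With the log2 GAPDH ratio as a covariate, added after the data were seen, no probe set passed in limma and 656 had an unadjusted p under 0.05. CDH1 then differed by 3.04 (SE 0.424, 95% interval 2.13 to 3.94, adjusted p = 0.0722).

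Among the genes fixed by name, CDH1 passed and the other 8 that were tested did not. N-cadherin (CDH2) differed by 0.60 (95% interval -0.13 to 1.32) on 1 probe set and by -0.18 (-0.65 to 0.28) on the other. Within the low and the high ribosomal RNA set the former was 0.31 and 0.26, both smaller than over all arrays. CTNNB1, which encodes beta-catenin, the cytoplasmic partner of cadherins, differed by 0.10 (-0.47 to 0.67). The tight junction genes OCLN, CLDN1 and TJP1 differed by 0.01 (-0.61 to 0.63), 0.20 (-0.43 to 0.83) and 0.07 (-0.34 to 0.49), and another TJP1 probe set by -0.41 (-0.99 to 0.17). Within the low and the high set OCLN differed by 0.32 and 0.23 and CLDN1 by 0.57 and 0.23, more than over all arrays. ABCC2, the bile canalicular export pump, differed by 0.05 (-0.42 to 0.52). Albumin (ALB), on its brightest probe set, had a signal of 5735 ± 412 (SD, n = 5) against 5711 ± 517 (SD, n = 4), a difference of 0.01 (-0.21 to 0.23), and its other probe sets differed by 0.62 (-0.60 to 1.84) and 0.21 (-0.31 to 0.73). The former of these other probe sets differed by 0.18 within the low and 0.29 within the high set. The latter differed by -0.18 and 0.65. The mesenchymal intermediate filament gene VIM was dim in both groups, at 3.09 ± 3.24 against 8.30 ± 4.21, and differed by -0.35 (-0.72 to 0.02). Limma adjusted p for these genes lay between 0.624 and 0.995. Intervals that reach 0.5 or more leave changes of that size open.

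Of the 22 gene lists fixed before the data were examined, 6 were shifted against the other genes by camera with its preset correlation of 0.01, 4 upward and 2 downward. None of the 22 passed with a correlation estimated from the arrays, where no list had an unadjusted p under 0.05. With fry, which asks whether a list moves one way against no change rather than against the other genes, none passed and 2 had an unadjusted p under 0.05. In all 22 lists, CDH1 was the only member that passed over all probe sets; further members named as examples were chosen after their values were seen, and none of those passed.

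The adherens junction and desmosome genes were higher: of 20 members tested, 1 rose, 0 fell and 19 did not pass, 15 had higher values, and the median difference was 0.33 (camera adjusted p = 0.00174). The adjusted p was 0.544 with an estimated correlation, and without knockdown 2 the median was 0.21. Adjusted over the list alone, 2 members passed, CDH1 and JUP, which encodes plakoglobin and differed by 1.07 (limma adjusted p = 0.426 over all probe sets), while VCL (vinculin) differed by 1.01 and CDH2 by 0.60. The integrin and matrix adhesion genes were also higher, with 17 of 23 members higher, 0 past the test over all probe sets and a median of 0.26 (camera adjusted p = 0.00515, adjusted p = 0.544 with an estimated correlation). Adjusted over the list alone, 1 passed, the integrin gene ITGAV with 1.05, and LAMB3, a laminin chain, and SDC4, a syndecan, differed by 1.05 and 0.90. The actin and small GTPase genes had a median of 0.18, with 17 of 25 higher and 0 passing, also 0 adjusted over the list alone (camera adjusted p = 0.00537, adjusted p = 0.554 with an estimated correlation). The myosin light chain gene MYL9 differed by 1.07 and RAPGEF2, an exchange factor for Rap GTPases, by 0.64. Without knockdown 4, the adjusted p was 0.0526 for the integrin list and 0.0609 for the actin list, whose median was then 0.11, against 0.10 without knockdown 1 and 0.34 without control 4.

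The interferon response genes were higher in 18 of 21 members, with a median of 0.13 and 0 passing over all probe sets (camera adjusted p = 0.00515, adjusted p = 0.544 with an estimated correlation). Adjusted over the list alone, 2 passed: IFIH1, an RNA sensor, differed by 0.68 and the transcription factor IRF1 by 0.64. OAS1, an antiviral enzyme, differed by 1.18. Without control 2 the adjusted p of the list was 0.0962 and its median 0.04, and the median was 0.23 without control 3 and 0.24 without control 4.

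The cell cycle genes were lower in 23 of 29 members, with a median of -0.20 and 0 passing, also 0 adjusted over the list alone (camera adjusted p = 0.00515, adjusted p = 0.607 with an estimated correlation). The centromere gene CENPA differed by -0.48, the mitotic kinase PLK1 by -0.58 and the replication licensing gene MCM3 by -0.50. Without control 1 the adjusted p of this list was 0.656 and its median -0.01, without control 4 the adjusted p was 0.0641, and without knockdown 4 it was 0.0889, with a median of -0.08. The median was -0.12 without knockdown 3 and -0.32 without knockdown 5. The integrated stress and unfolded protein response genes were lower in 19 of 21 members, with a median of -0.31 and 0 passing, also 0 adjusted over the list alone (camera adjusted p = 0.000335, adjusted p = 0.555 with an estimated correlation). SLC7A5 and SLC3A2, which encode the chains of an amino acid transporter, differed by -0.67 and -0.64, the serine synthesis gene PSAT1 by -0.91 and the transcription factor ATF4 by -0.41. The stress list moved with the array sets and the RNA quality measure: its adjusted p was 0.0376 with the array set as a block, 0.455 in the low ribosomal RNA set alone (median -0.11), 0.389 with the GAPDH ratio as a covariate (median -0.08) and 0.0962 without control 2 (median -0.17). For the 5 other shifted lists the adjusted p in the low set alone ran from 5.36e-10 (cell cycle) to 0.0300 (interferon response). The cell cycle list moved with the array sets too, with a median of -0.51 in the low set alone and -0.26 with the array set as a block, and its adjusted p was 1.21e-05 with the GAPDH ratio as a covariate. With that covariate the median of the adherens junction and desmosome list was 0.13 (camera adjusted p = 0.00511) and that of the integrin and matrix adhesion list 0.15 (camera adjusted p = 0.0156).

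**Figure D3:**
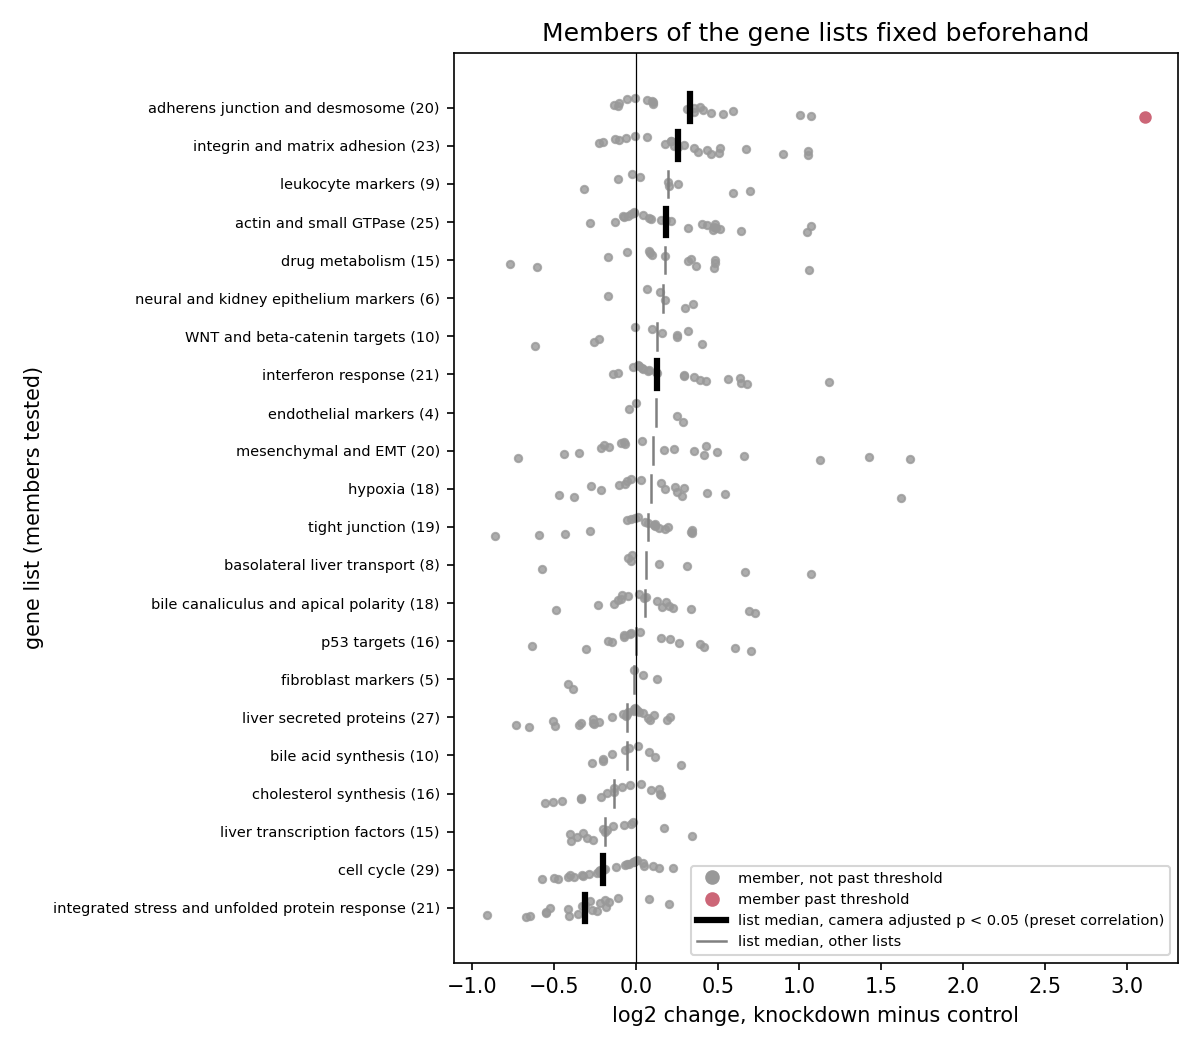
Each point is 1 gene's log2 difference between knockdown and control arrays, grouped by the 22 lists fixed beforehand with the number of members tested in brackets. Vertical bars mark list medians, thick for the 6 lists shifted by camera with its preset correlation, and the single red point at 3.11 is CDH1, the 1 member past the limma test.

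The junction and polarity lists other than that of adherens junctions were not shifted. Tight junction genes had a median of 0.07 over 19 members, with 0 passing, while their mean was -0.01 and the camera direction was down (adjusted p = 0.713). Adjusted over the list alone, 1 passed, CXADR, a tight junction adhesion protein, with -0.86, and SYMPK differed by -0.59. Bile canaliculus and apical polarity genes had a median of 0.06 over 18 members (camera adjusted p = 0.513), with 0 passing and 1 adjusted over the list alone, the microvillar protein gene VIL1 with 0.73, and EZR (ezrin) differed by 0.69. Basolateral liver transport genes had a median of 0.06 over 8 members (camera adjusted p = 0.475), with 0 passing and 1 adjusted over the list alone, the export pump gene ABCC3 with 1.07, and the uptake carrier gene SLCO2B1 differed by 0.66.

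Liver function lists held no member that passed. Liver secreted proteins were lower in 19 of 27 members, with a median of -0.05 (camera adjusted p = 0.0517), 0 adjusted over the list alone, and the fibrinogen chains FGA and FGB at -0.65 and -0.49. Liver transcription factors were lower in 13 of 15 members, with a median of -0.19 (camera adjusted p = 0.0505), 0 adjusted over the list alone, and CEBPB at -0.40 and the nuclear receptor NR1H3 at -0.30. Cholesterol synthesis genes had a median of -0.13 over 16 members (camera adjusted p = 0.151), 0 adjusted over the list alone, with SQLE at -0.56 and FDPS at -0.45. Bile acid synthesis genes had a median of -0.05 over 10 members (camera adjusted p = 0.573), 0 adjusted over the list alone, with CYP7A1, the rate-limiting enzyme of the classical pathway, at 0.27 and BAAT at -0.20. Drug metabolism genes had a median of 0.18 over 15 members (camera adjusted p = 0.151), and 1 passed adjusted over the list alone, the cytochrome gene CYP3A5 with 1.06, while SULT1A1 differed by 0.48.

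Mesenchymal and EMT genes were not shifted as a list (median 0.11 over 20 members, camera adjusted p = 0.345), and 0 passed over all probe sets. Adjusted over the list alone, 4 passed: the actin-binding genes TPM1 and TAGLN with 1.12 and 1.68, the matricellular gene CCN1 with 1.42, and ZEB1, a transcriptional repressor of CDH1, with -0.72. TPM1 passed over all probe sets when knockdown 3 was left out (1.31, limma adjusted p = 0.0415). That fit mixes group with array set, so the pass is not further evidence for TPM1. The TPM1 difference was smaller than 1.31 within each array set. Its log2 signal was 8.48 and 8.63 in control 2 and control 3 of the high set. In control 1 and control 4 of the low set it was 9.07 and 9.28. WNT and beta-catenin targets had a median of 0.13 and a mean of 0.04 over 10 members, while the camera direction was down (adjusted p = 0.815), 0 passed adjusted over the list alone, and MYC differed by -0.62 and GLUL by -0.25. The p53 targets had a median near 0 and a mean of 0.08 over 16 members, with the camera direction up (adjusted p = 0.760), 0 adjusted over the list alone, TP53I3 at 0.70 and CCNG1 at -0.30. Hypoxia genes had a median of 0.09 over 18 members (camera adjusted p = 0.717), 0 adjusted over the list alone, with the glucose transporter gene SLC2A3 at 1.62 and HK2 at -0.47. For MYC, TP53I3 and SLC2A3 the differences within the array sets were smaller in size than those over all arrays. In the low and the high set they were -0.48 and -0.40 for MYC, 0.51 and 0.24 for TP53I3, and 1.30 and 0.81 for SLC2A3.

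Markers of other cell types were not shifted between the groups, and 0 passed in any of the 4 lists, also adjusted over the list alone. Endothelial markers had a median of 0.12 over 4 members (camera adjusted p = 0.545) with FLT1 at 0.29 and TIE1 at 0.25, and leukocyte markers 0.20 over 9 (adjusted p = 0.474) with CD3D at 0.59 and LYZ at 0.70. Fibroblast markers had a median of -0.01 over 5 members (adjusted p = 0.435) with DCN at -0.39 and PDGFRB at -0.41, and neural and kidney epithelium markers 0.16 over 6 (adjusted p = 0.345) with PAX2 at 0.30 and PAX8 at 0.35.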

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

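The tests of the array sets, of the CDH1 difference within array sets and of the list calls were chosen after those results were seen. The tests of CDH1 with the GAPDH ratio and without single arrays, and the counts over other splits of the arrays, were chosen before their results were seen.

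In 7 of 86 groups of values examined (8.14%), 1 array stood apart from the rest of its group by Dixon's criterion, where chance alone gives about 1 in 20. The CTNNB1 log2 signal of knockdown 1 was 7.40, below the 8.47 to 8.54 of the other knockdown arrays. The OCLN log2 signal of knockdown 3 was 6.93, above the others at 5.91 to 6.12. On ALB probe set 214837_at, knockdown 4 had a log2 signal of 6.58 against 7.17 to 7.40. The dim probe sets of DCN in knockdown 1 (4.75 against 4.11 to 4.18) and of FLT1 in control 3 (4.07 against 4.29 to 4.32) lay close to the floor of 4. Among array measures, knockdown 3 had a ribosomal RNA signal of 18.5 times its median against 1.60 to 3.34 in the other knockdown arrays, and control 4 had a median signal of 26.4 against 16.9 to 18.2.

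For the CDH1 difference, an unequal share of the array sets would require overlap of the groups within sets. The lowest knockdown array lay 1.91 above the highest control array within the low ribosomal RNA set and 2.20 above it in the high set. The groups did not overlap over all arrays, so they could not overlap within a set. The outcome was thus fixed beforehand and could not decide the question. RNA degradation tracked by the GAPDH ratio would take the difference below 1, but it was 3.04 with the ratio as a covariate (95% interval 2.13 to 3.94) against 3.11 (2.30 to 3.92) without it. The call itself ended there, at an adjusted p of 0.0722, as the SE went from 0.376 to 0.424. With any single array left out the difference stayed at 2.87 or more, so its size did not rest on 1 array. Since the groups did not overlap, leaving out 1 array could not have removed the difference. That outcome was fixed beforehand too and could not decide whether a single array was the cause. The call did depend on single arrays. Its limma adjusted p stayed under 0.05 only without control 2, knockdown 3 or knockdown 5, and was 0.0880 without knockdown 2. That the knockdown lies behind the difference is a hypothesis from the same data, which these tests do not establish. The selection of transduced cells and the unreported level of the target stayed untested.

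The array sets themselves were weighed next. The 2 ratios of 3′ to 5′ signal that had not defined the sets, those of GAPDH and actin, both separated them without overlap, which is consistent with a difference in RNA quality or labelling between the sets. The knockdown cannot account for the sets, since both groups were present in each and 3 arrays lay in the set where their group was in the minority. The titles of the 3 high-set arrays also differ in form from those of the other 6, since 2 leave out the cell line and 1 adds an array type. The labels name no run or batch, so the origin of the sets stayed open.

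The shifts of gene lists were the last pattern weighed. Correlation between genes within arrays remains a possible explanation for all of them, since 0 lists passed with an estimated correlation. At the preset correlation, 5 of the 6 lists kept their call and direction with the array set as a block. They also kept both in the low ribosomal RNA set alone. At that correlation, membership in the 2 sets thus did not account for the whole of these shifts. Differences between arrays inside a set were not tested as a cause. The low set holds only 2 control arrays, however, and the cell cycle call rested on 1 of them. Without control 1 the median of that list was -0.01 (camera adjusted p = 0.656). For the integrated stress and unfolded protein response list an unequal share stayed open as a cause. Its median went from -0.31 to -0.16 with the block (camera adjusted p = 0.0376). In the low set alone, which holds fewer arrays, it was -0.11 (camera adjusted p = 0.455). As many lists passed in 27 of 100 splits of the 9 arrays, the real split included, with 6 in the real split and at most 10 in another, and in 10 of the 36 other drawn splits with the same share of array sets, so chance could not be excluded.

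Chance could not be excluded for the number of changed probe sets either, since 6 of 100 splits, the real one included, gave at least the 6 of the real split. The highest other count was 1281, from a split whose group of 5 came wholly from the low ribosomal RNA set, which points to the structure of the arrays; with the array set as a block the real split gave 7. Of the 5 other splits with counts as large, 2 had 5 and 3 had 2 arrays of the low set in the group of 5. In the 36 drawn splits with 4 such arrays, as in the real one, the highest count was 1, a comparison made after the result was seen. For probe sets without overlap, 11 of 100 splits gave at least the real 395, with 1584 the highest other, again from a split with 5 arrays of the low set in 1 group, so chance could not be excluded there. Counts as large came from 6 of the 10 splits with 2 arrays of the low set in the group of 5, from 3 of the 3 others with 5, from 0 of the 50 with 3, and from 1 of the 36 other splits with 4, as in the real one.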

How the results depend on the processing

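The settings with the array set, the low ribosomal RNA set alone and the GAPDH ratio were chosen after the data were seen. The number of changed probe sets, 6, was 2 with a pseudocount of 1, 0 with no filter on dim probe sets (1603 at an unadjusted p under 0.05 in limma), 0 at an adjusted p under 0.01, 2 in the low ribosomal RNA set alone and 0 with the GAPDH ratio as a covariate (656 unadjusted). With 1 array left out it ranged from 0 to 36. The cause was not tested, except that the low set alone holds fewer arrays. With the title number as a replicate block the number of changed probe sets was 2. Same-numbered arrays deviated with correlations of -0.15, 0.54 and 0.24. Control 1 and knockdown 1, which have no number and shared a block, deviated with 0.38. These values were mixed, so the numbers were not taken to pair the arrays. The other settings gave 5 to 9. With the deposited scaling 4 of 6 rose and 2 fell, against 2 and 4 with quantile normalization, and SRM then had an adjusted p of 0.194. The number of shifted lists, 6, was 0 with an estimated correlation (0 unadjusted). In those 6 lists the estimate ran from 0.11 (interferon response) to 0.63 (cell cycle), in place of the preset 0.01. Fry, which tests a list against no change rather than against other genes, gave 0 (2 unadjusted). The other settings gave 4 to 9 shifted lists. The level of the targeted gene was not analysed here under any setting. Over 39 named probe sets and 886 alternatives, 803 kept direction and side of the threshold, 56 lost the call and 1 gained it. The other 26 changed sign in genes that had not passed, and no called gene or shifted list changed direction. Only the 5 called genes could lose a call. CDH1 lost it in 8 of 23 alternatives, SCNN1A in 10 of 23 and DESI2 in 12 of 23. SRM lost it in 13 of 23 and SLC25A14 in 13 of 22. The 5 called genes kept their sign in every setting that tested them (all but the 50% filter on dim probe sets for SLC25A14, which it left out), with log2 differences of 2.24 to 3.68 for CDH1, 0.94 to 2.39 for SCNN1A, -1.86 to -1.25 for DESI2, -1.74 to -1.17 for SRM and -2.48 to -0.41 for SLC25A14, whose signal near the floor limits its fold. Adjusted p for CDH1 ranged from 8.79e-05 to 0.0880.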

Other observations

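The epithelial and the growth gene lists below and the tests on them were chosen after CDH1, SCNN1A, SRM, MYC and the genes named next had been seen, and before the values of their members were examined, except the test without the dimmer probe sets, which was chosen afterwards.

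The 25 genes with the smallest p among those that did not pass, with groups that did not overlap, were listed after the values were seen. BICC1, an RNA-binding protein gene, was 2.51-fold higher in knockdown arrays (limma adjusted p = 0.0918), and BLVRA, which encodes biliverdin reductase, 2.46-fold higher (adjusted p = 0.110), with a signal of 738 ± 147 (SD, n = 5) against 296 ± 83.5 (SD, n = 4). LGALS3, which encodes the lectin galectin-3, was 2.99-fold higher (adjusted p = 0.189) and the tetraspanin gene TSPAN1 2.72-fold higher (adjusted p = 0.298). The water channel gene AQP3, 1.83-fold higher, and the cytoskeletal linker gene DST, 2.04-fold higher, had an adjusted p of 0.253. The interferon-induced gene GBP1 was 1.91-fold higher (adjusted p = 0.265). AKTIP was 2.53-fold lower (adjusted p = 0.162), and NME1, a nucleoside diphosphate kinase gene, 1.70-fold lower (adjusted p = 0.265).

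Because CDH1 and SCNN1A are epithelial genes, a list of 24 other epithelial genes was tested, of which 19 were on the tested probe sets. Values were higher in knockdown arrays for 18 of the 19, the median difference was 0.37, and 0 members passed over all probe sets in limma. Camera gave p = 9.81e-07 with its preset correlation and p = 0.0172 with an estimated correlation, and with the array set as a block the median was 0.34 and the estimated-correlation p was 0.0222. The keratin gene KRT19 differed by 1.62, the surface protein gene CD24 by 1.28 and LAD1 by 0.75. Many members were dim, with mean control signals of 4.41 for KRT7 and 6.28 for SPINT1, and GRHL2, also dim, differed by -0.24. With the dimmer 50% of all probe sets left out, 10 members dropped out and the other 9 all had higher values, with a median of 0.64 and an estimated-correlation p of 0.0347, or 0.0444 with the array set as a block. A median as far from 0 was given by 4 of 100 splits, the real one included, with 0.43 the largest other, and by 0 of the 36 splits with the same share of array sets. For this list no value is given with the GAPDH ratio as a covariate, in the low ribosomal RNA set alone or without single arrays. A broader rise of epithelial transcripts may accompany that of CDH1, which is a hypothesis found and tested on these arrays.

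Because SRM, MYC and NME1 were lower, a list of 26 other growth genes driven by MYC was tested, of which 20 were on the tested probe sets. Values were lower for 15 of the 20, with a median of -0.12 and 0 members past the limma test. Camera gave p = 0.0144 with its preset correlation and p = 0.194 with an estimated correlation, and with the array set as a block p = 0.0897 with an estimated correlation. The nucleolar genes FBL and NCL differed by -0.28 and -0.22 and the transferrin receptor gene TFRC by -0.25. A median as far from 0 came from 19 of 100 splits, the real one included, with 0.19 the largest other, so chance could not be excluded and a lower MYC-driven program could not be told from the spread between arrays.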
